A study of Mus musculus with 9 samples.

How the data were processed

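RNA sequencing libraries of 9 samples were made from sorted neural crest cells of C57BL/6 mouse embryos at E9.5, in 3 groups of 3: wild type with PBS, wild type with ET-1 and a Mef2c neural crest conditional mutant with ET-1. Per the labels' protocols, RNA was taken up with a column kit for small samples and amplified to cDNA with a NuGEN Ovation kit, and barcoded libraries were made with a NuGEN Encore multiplex kit. TopHat 1.3.1, Cufflinks 1.3.0, Cuffdiff and the genome build mm9 are named in the submitters' processing notes, without their settings. Read length, sequencer and the way in which replicates were combined are not given in the sources used here.

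The table of 33495 genes held, per the file headers, an FPKM value that the authors computed for each group and not for each sample. It also held, per the file headers, a p-value from the authors for ET-1 against PBS and a p-value for the mutant against wild type with ET-1. A second table listed the genes that the authors called induced, with a normalized induction fold made by the authors, a MEF2 motif mark and a Mef2c dependence mark. The p-values in the deposited columns were judged to be unadjusted, because nearly every gene had a value of its own. The test behind them is not given in the sources used here, although Cuffdiff is named in the submitters' processing notes.

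In 15639 genes both wild-type values were whole numbers up to 17 and 15 and the deposited p-value was exactly 1, and 10404 of these held 0 in both groups. These numbers looked like raw reads of genes too low to test and were not used as FPKM. FPKM was present in both wild-type groups for 17856 genes and in all 3 groups for 17757. In 1440 genes the mutant value was FPKM and the wild-type values were whole numbers, and these were kept out of all comparisons. There were 0 columns belonging to other samples.

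A test was planned on FPKM per sample, or on adjusted p-values from the authors if only group values were given. The tables analysed here held group values and unadjusted p-values. Therefore the p-values of the authors' deposited table were adjusted by the Benjamini-Hochberg method over genes with FPKM in both groups and at least 1 FPKM in either, and a gene was called at an adjusted p under 0.05. The words rose, fell, higher and lower refer to these calls for genes. The log2 fold is log2 of the ratio of FPKM + 1 in each group, which understates the change of low genes. The largest unadjusted p among called genes was 0.000260 for ET-1 and 0.00246 for the mutant in the authors' deposited table.

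The deposited p-values followed the pooled reads in most genes. Among sets of genes with the same pair of pooled read numbers, the deposited p-values of the authors differed by a median of 0.595% for ET-1 (3490 genes) and 1.04% for the mutant (2342 genes). The 95% quantile of this difference was 42.5% and 33.6%, and the largest was 595% and 4374%. Genes next to each other in total reads differed by a median of 74.4% and 124%. These neighbours were not matched on the ratio of their reads, so larger differences there follow by construction. A spread fitted to the level of a gene would also give equal p-values to equal reads, and the p-values were larger than counting error alone would give: Rpl4, with a counting interval of 1.13 to 1.16 for its fold in the mutant, had an adjusted p = 0.860 computed from the authors' deposited table. How far the p-values held the spread between embryos of a group is not known. The labels do not say whether samples of a group came from separate embryos or from pools. Of 17856 genes, 728 had a deposited p-value of the authors under 0.05 for ET-1, where 893 would if p were uniform, and for the mutant 1855 of 17757, against 888.

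Pooled reads were recovered from FPKM. In genes with a single exon the FPKM values came out as whole reads, within 0.02 of a whole number, for 93.6% of 1263 genes with PBS, 93.8% of 1264 with ET-1 and 93.8% of 1263 in the mutant. For other genes the model length was the smallest that gave whole reads in all 3 groups without exceeding the gene's span, times the multiple nearest the exon length in GENCODE M21. Reads were recovered for 17756 of 17757 genes, and 98.3% of 16401 lengths lay within 2-fold of the GENCODE M21 exon length. A wrong length would change the width of an interval and not the fold itself. Reads summed over genes came to 132% of the group total with PBS, 132% with ET-1 and 135% in the mutant. Some reads may have been counted in several genes, or model lengths may have been too long, and these were not told apart.

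Fold intervals are exact Clopper-Pearson 95% intervals from the pooled reads and cover counting error only, since reads amplified by PCR are not independent molecules. Bootstrap intervals are 95% intervals that resample genes, so they cover the spread over genes and not the spread between embryos. They treat genes as independent, which does not hold for copies of the same parent gene. The total per group was 21507319, 19801230 and 46930101 reads for PBS, ET-1 and the mutant. Coordinates are those of the authors' table in mm9, counted from 1 after 1 was added to each start, since 37 of 37 mitochondrial genes began 1 base before their annotated start. GENCODE M21, an annotation of a later build, was used only for gene classes, current names and transcript sequences, and 28692 of 33495 gene identifiers matched it. The share of 50-base words is the percentage of such words in a gene's longest transcript that also occur, on either strand, in a transcript of another gene.

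Before the data were examined, 25 gene lists were fixed for signalling pathways, arch and crest identity, other cell types, stress, cell cycle and housekeeping functions. For each list with at least 3 measured members, the median log2 fold was placed among 10000 random lists of the same size matched in 10 expression bins. This percentile describes the group values and is not a test across replicates. The rule for named genes was also fixed then. It took Mef2c, the 10 largest rises and 10 largest falls among called, named genes of each comparison, up to 4 called members of each list with the largest change or otherwise the 2 most abundant, up to 10 genes of the overlap with the largest product of folds, and 8 textbook endothelin genes. Models named after genomic clones and names shared by several genes were treated as unnamed, a choice made after the data were seen. Other genes named in the text were chosen after their values were seen. A gene that the rule selected is not reported here.

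For the overlap, the number of genes shared by independent lists was set beside a simulation of 100 runs without effects, in which the ET-1 wild-type value was shared and the spread was the one implied by the deposited p-values of the authors. Alternatives were a stricter or unadjusted threshold, a minimum fold of 1.5 or 2, other filters on low values, a pseudocount of 0.1, re-centring on the median, unmatched random lists and the authors' deposited list. A simulation of the same kind, added after the data were seen, gave the position of the mutant against PBS for genes called for ET-1, since both rest on the same PBS value. An unadjusted p under 0.05 and a restriction to protein-coding genes sharing under 10% of their 50-base words, with p adjusted over these genes alone, were also added after the data were seen, and so was leaving Mef2c, the mutated gene, out of the overlap and the lists.

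The steps were tested on simulated data. Given a true length as guide, reads were recovered for 99.85% of 2000 simulated genes. In the simulated ET-1 comparison of 15545 genes, 24.6% of genes changed 1.5 times, 74.3% of those changed 2 times and 94.2% of those changed 4 times were called in the right direction, and 4 of 136 called genes had not been changed. In the simulated mutant comparison of 15516 genes the values were 27.4%, 70.0% and 94.1%, and 9 of 139 called genes had not been changed. Of 100 opposite changes planted in both comparisons, 57 were called in both. The simulated p-values used the same spread that the reads were drawn with. These shares therefore test the steps and give no error rate for the real calls. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.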

Results

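RNA was sequenced from neural crest cells of mouse embryos at E9.5. The neural crest is a migratory embryonic cell population that gives rise to facial skeleton, peripheral neurons, glia and pigment cells. Embryo explants recovered in culture for 1 h, were exposed to 10 µM endothelin-1 (ET-1) or to phosphate-buffered saline (PBS), and were cultured for 12 to 15 h before genetically labelled neural crest cells were sorted. ET-1 is a secreted peptide that acts on the pharyngeal arch crest through the endothelin A receptor. The 9 samples fell into 3 groups of 3: wild type with PBS, wild type with ET-1, and a neural crest conditional mutant of the transcription factor gene Mef2c with ET-1. The table analysed here held a single FPKM value per group (fragments per kilobase of transcript, scaled to the reads of the group), so no value had a replicate error.

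Depth was recovered from the values of genes with a single exon, as pooled reads per group. It came to 21507319 reads for wild type with PBS, 19801230 for wild type with ET-1 and 46930101 for the mutant with ET-1. A transcript of 1 kb at 1 FPKM thus rested on 21.5, 19.8 and 46.9 pooled reads. The mutant group was 2.37 times as deep as the ET-1 wild-type group and 2.18 times as deep as the PBS group. All fold intervals given here are 95% exact counting intervals from pooled reads and cover counting error only, not the spread between embryos.

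Mef2c, which encodes a MADS-box transcription factor, rose with ET-1 in wild type and was lower in the mutant. The gene (ENSMUSG00000005583) lies on mouse chromosome 13 at 83643194 to 83802927 in build mm9. Its level was 7.71 FPKM with PBS, 25.2 FPKM with ET-1 and 10.1 FPKM in the mutant with ET-1. The rise with ET-1 was 3.27-fold (interval 3.13 to 3.42), with an adjusted p = 5.44e-12 computed from the p-values in the authors' deposited table. The mutant held 0.401 of the ET-1 wild-type level (interval 0.389 to 0.414), with an adjusted p = 6.52e-11 from the authors' deposited table. FPKM was given over the whole gene model, so the loss of a single exon would not show as such.

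The first comparison set sorted wild-type cells with ET-1 against those with PBS, and 60 genes rose and 22 fell among 15395 tested. A group value does not tell regulation within cells from a different mix of the sorted cells. Among the genes with the largest rises, Tmem121, a transmembrane protein gene, went from 0.266 to 3.88 FPKM, a 14.6-fold rise (interval 7.44 to 32.7). Hs3st1, a heparan sulfate sulfotransferase, rose 9.78-fold from 0.375 to 3.67 FPKM (interval 5.99 to 16.9). Plxna4, a semaphorin co-receptor, rose 4.79-fold from 2.01 to 9.62 FPKM (interval 4.33 to 5.30), and Thbs1, the matrix glycoprotein thrombospondin 1, rose 3.96-fold from 3.48 to 13.8 FPKM (interval 3.57 to 4.40). Gfra3, the artemin co-receptor, went from 2.15 to 8.35 FPKM, and Nr4a1, an inducible orphan nuclear receptor, from 3.15 to 10.4 FPKM. Grik1, a kainate receptor subunit, rose from 0.460 to 2.76 FPKM, Colec12, a scavenger receptor, from 4.33 to 13.1 FPKM, and Mcam, a cell adhesion molecule, from 5.82 to 15.7 FPKM.

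Among the 22 genes that fell with ET-1, 9 were named genes and the others were unnamed models. Afp, the fetal plasma protein alpha-fetoprotein, fell from 3.12 to 0.452 FPKM, and Gli1, a transcription factor induced by hedgehog signalling, from 4.83 to 1.72 FPKM. Adamts20, a secreted metalloprotease, fell from 10.3 to 5.96 FPKM, Dcx, the neuronal microtubule protein doublecortin, from 8.17 to 4.69 FPKM, and Frem1, a basement membrane protein, from 3.21 to 1.72 FPKM. Txndc11 fell from 7.61 to 4.54 FPKM, Cwc22, a splicing factor, from 31.8 to 19.7 FPKM, Nnat from 109 to 74.4 FPKM, and Scd2, a stearoyl-CoA desaturase, from 226 to 169 FPKM, a call lost without the filter on low values. The median fold of the genes that rose was 1.78 and that of the genes that fell was 0.505. With a further requirement of a fold of at least 2, 22 genes rose and 11 fell. Of the calls without that requirement, 54 rises and 8 falls were in protein-coding genes that share little sequence with other genes, and with p adjusted over such genes alone, a choice made after the data were seen, 56 rose and 10 fell.

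The list of immediate early and MAP kinase feedback genes had the largest median of the fixed lists with ET-1. Of 28 measured, 5 rose and 0 fell (9 and 0 adjusted over the list alone), and the list's median log2 fold was 0.38, at the 100 percentile of matched random lists. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, rose from 1.68 to 5.42 FPKM, Ctgf, a matricellular growth factor, from 20.5 to 36.2 FPKM, and Nr4a3 from 3.77 to 7.26 FPKM. Of the neural crest and neuroglial genes, 5 of 19 rose (6 higher and 1 lower adjusted over the list alone; median 0.28, percentile 100). These were the transcription factor genes Sox10 (35.7 to 61.0 FPKM), Ets1 (13.6 to 31.7 FPKM) and Tcfap2b (17.7 to 26.4 FPKM), the neurotrophin receptor gene Ngfr (23.4 to 39.0 FPKM) and the neuregulin receptor gene Erbb3 (20.1 to 31.7 FPKM).

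Further lists lay above the central 95% of random lists. In the list of MEF2 factors, class IIa histone deacetylases and MEF2 targets, Mef2c and Nr4a1 rose among 13 measured (3 higher and 1 lower adjusted over the list alone; median 0.20, percentile 99.4). Without the filter on low values the median of this list was 0.15 and lay inside the central 95%. Of 11 smooth muscle genes, 1 rose, the tropomyosin gene Tpm1, by 1.84-fold from 16.2 FPKM (1 adjusted over the list alone; median 0.25, percentile 99.9). Of 11 extracellular matrix and skeletogenic genes, 1 rose, Thbs1 (5 adjusted over the list alone; median 0.20, percentile 99.0). Among 20 genes of mitosis and DNA replication 0 passed the test, also adjusted over the list alone, and the median was 0.09 (percentile 99.2, which was inside the central 95% when random lists were not matched on expression). Mki67 was at 93.5 FPKM with PBS and 97.3 FPKM with ET-1.

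Lists below the central 95% with ET-1 were the dorsal or maxillary arch genes, Notch signalling genes and ribosomal proteins. Among 10 dorsal or maxillary genes 0 passed the test over all genes (2 lower adjusted over the list alone; median -0.29, percentile 0.02). Among 10 Notch genes 0 passed (1 lower adjusted over the list alone; median -0.21, percentile 0.14). Among 20 ribosomal protein genes 0 passed on either count (median -0.21, percentile 0.08), and the most abundant of them stood at 875 and 886 FPKM for Rpl3 and 959 and 912 FPKM for Rpl4. In all, 9 of 21 lists with at least 3 measured members lay outside the central 95%, where 1.05 would for lists of independent genes. Members of a list may vary together and some genes are in several lists, so the 1.05 is no measure of chance here.

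The remaining lists lay inside the central 95% with ET-1 under the settings used throughout. For the endothelin-dependent ventral arch programme, 1 of 9 measured members rose, Mef2c (1 higher and 1 lower adjusted over the list alone; median 0.17, percentile 96.7). No member passed the test among 17 G protein signalling genes (median 0.06), 11 p53 and apoptosis genes (0.04), 15 hypoxia and glycolysis genes (-0.0011), 13 BMP genes (-0.03), 8 WNT targets (0.06, and 0.22 and above the central 95% at 5 FPKM or more in either group) and 18 respiratory chain genes (-0.02), and the count was also 0 adjusted over each list alone. Among 11 genes of endoplasmic reticulum and heat stress 0 passed (1 lower adjusted over the list alone; median -0.02). Of markers of other cell types 0 passed: 5 erythroid genes had a median of 0.08, 4 epithelial genes -0.30, 4 mesodermal genes 0.12 and 6 neural tube genes -0.16. The most abundant neural tube markers were well expressed, Sox2 at 38.7 and 40.3 FPKM and Neurog2 at 25.8 and 23.3 FPKM with PBS and ET-1. The neural tube list lay below the central 95% with a pseudocount of 0.1 (median -0.20) and at 5 FPKM or more in either group (-0.25), and the epithelial list against random lists not matched on expression. Cardiac muscle, endothelium and macrophages had 1 measured gene each, Actc1 (2.87 and 4.59 FPKM), Egfl7 (1.65 and 1.66 FPKM) and Cd68 (5.70 and 5.54 FPKM), and the cytokine list had 2, Csf1 (1.25 and 1.58 FPKM) and Kitl (1.60 and 1.98 FPKM), with 0 called.

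**Figure D1:**
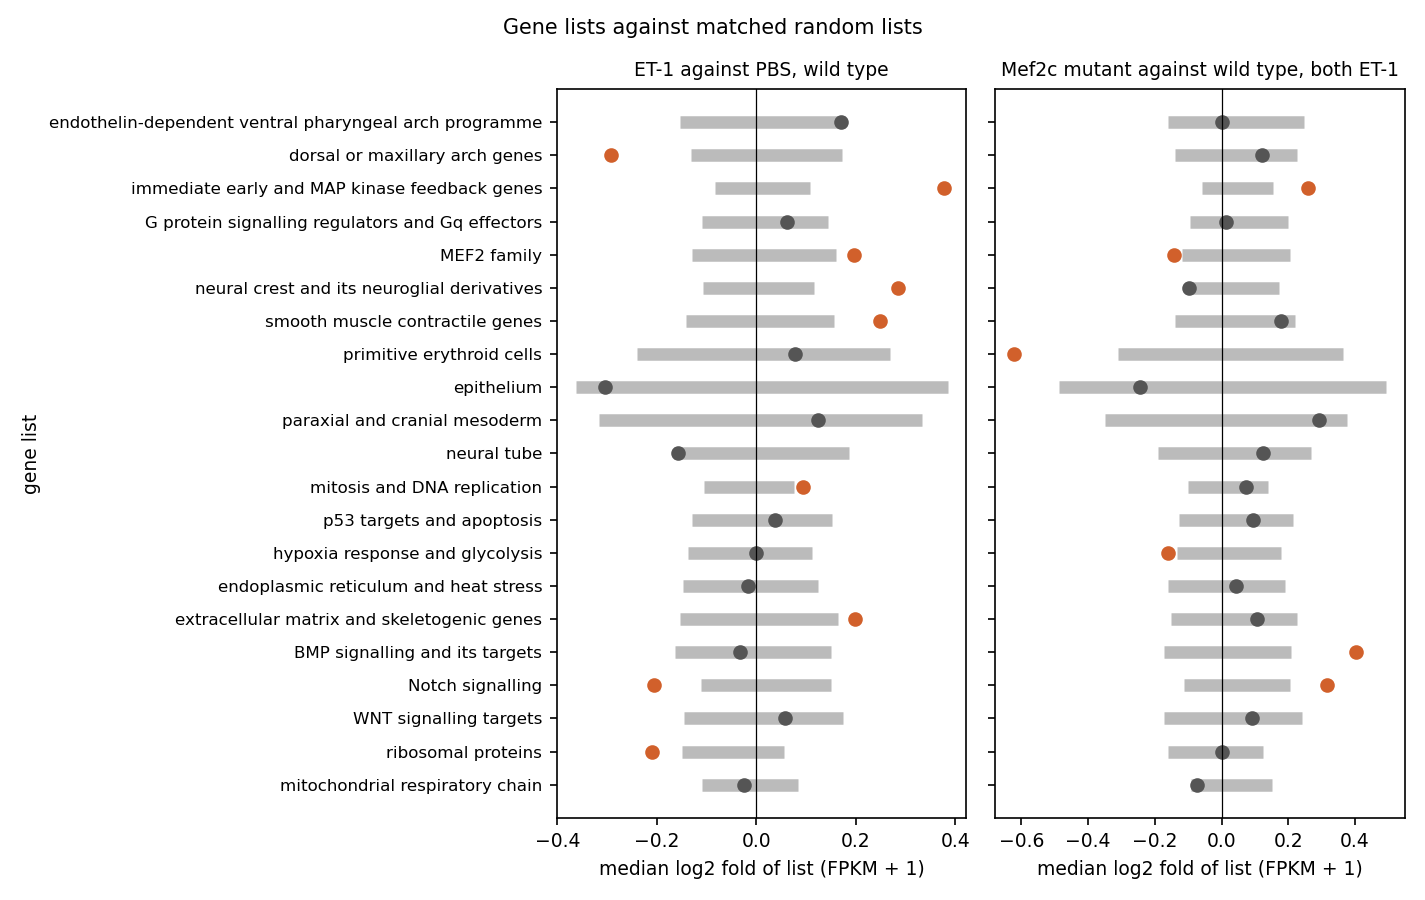
Median log2 fold of each fixed gene list (x axis, log2 of FPKM + 1; points) for ET-1 against PBS in wild type (left) and for the Mef2c mutant against wild type with ET-1 (right). Grey bars span the central 95% of 10000 random lists matched on expression, orange points lie outside them, and the row "MEF2 family" is the list of MEF2 factors, class IIa histone deacetylases and MEF2 targets; immediate early genes lie above the bar on both sides (0.38 and 0.26).

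The second comparison set mutant against wild type, both with ET-1, and 183 genes were higher and 580 lower in the mutant among 15459 tested. No mutant was given PBS, so a difference present without ET-1 cannot be told apart from a changed response to ET-1. Egr3, an inducible zinc finger transcription factor, rose 3.86-fold from 2.82 FPKM in wild type to 10.9 FPKM in the mutant (interval 3.06 to 4.94), and its relative Egr2 from 3.82 to 9.04 FPKM. Hes5, a transcriptional repressor induced by Notch, rose 3.23-fold from 14.1 to 45.4 FPKM (interval 2.93 to 3.57), and Prdm12, a regulator of sensory neuron formation, from 6.40 to 18.6 FPKM. Fhl2, a LIM domain protein, went from 0.446 to 3.36 FPKM, H2-Ab1, a class II histocompatibility chain, from 2.83 to 9.40 FPKM, P2rx5, an ATP-gated channel, from 0.253 to 2.02 FPKM, and Frzb, a secreted WNT antagonist, from 2.29 to 6.36 FPKM. Klf4, a zinc finger transcription factor, went from 1.45 to 4.35 FPKM and Car3, a carbonic anhydrase, from 0.442 to 2.21 FPKM, a call lost without the filter on low values.

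Among the largest falls in the mutant, Gadl1, an amino acid decarboxylase, went from 11.8 to 1.54 FPKM, or 0.131 of wild type (interval 0.114 to 0.150). Slc15a2, a peptide transporter, went from 8.52 to 0.972 FPKM, or 0.114 (interval 0.101 to 0.128). Tmem121 went from 3.88 to 0.230 FPKM, or 0.0593 (interval 0.0334 to 0.0989). The other large falls were in genes that share sequence with copies, for which the split of reads is uncertain. They included the chemokine copies Ccl21a (9.69 to 1.74 FPKM), Ccl21b (8.48 to 1.32 FPKM) and Ccl21c (8.96 to 1.37 FPKM), Psme2b-ps (5.84 to 0.937 FPKM), and the processed pseudogenes Dynlt1-ps1 (57.8 to 13.6 FPKM) and Hmgn4 (27.8 to 7.35 FPKM). Of the calls over all genes, 103 higher and 88 lower were in protein-coding genes that share little sequence with other genes, and with p adjusted over such genes alone, a choice made after the data were seen, 57 were higher and 48 lower. The calls of Car3 above and of Fosl2, Id1, Pdk1, Ets1 and Cd68 below were lost under that adjustment. Genes that share more sequence were not tested under it, such as Bnip3 and Cwc22 below (62.4% and 31.9% of their 50-base words). Hes5 above and Vcl below were not among the genes called there. With a fold of at least 2 over all genes, 60 were higher and 353 lower.

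By annotated class, protein-coding genes outside the histone clusters were higher in 127 and lower in 126 of 11808 cases in the mutant (median log2 fold 0.06). Processed pseudogenes, which are retrotransposed copies of mRNAs, were lower in 282 and higher in 3 of 1127 (median -0.34), and transcribed processed pseudogenes were lower in 17 of 57 (median -0.29). Histone cluster genes, whose mRNAs mostly lack a poly(A) tail, were lower in 49 and higher in 0 of 62 (median -0.84), and their median level was 123 FPKM with PBS, 135 FPKM with ET-1 and 65.3 FPKM in the mutant. Models without a match in the annotation were higher in 31 and lower in 94 of 1152. In the ET-1 comparison, 2 of 1136 processed pseudogenes and 0 of 63 histone cluster genes were lower. Processed pseudogenes with at least 50% of their 50-base words in another gene had a median log2 fold of -0.64 in the mutant (222 of 523 lower), against -0.12 for those under 10% (6 of 218 lower).

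**Figure D2:**
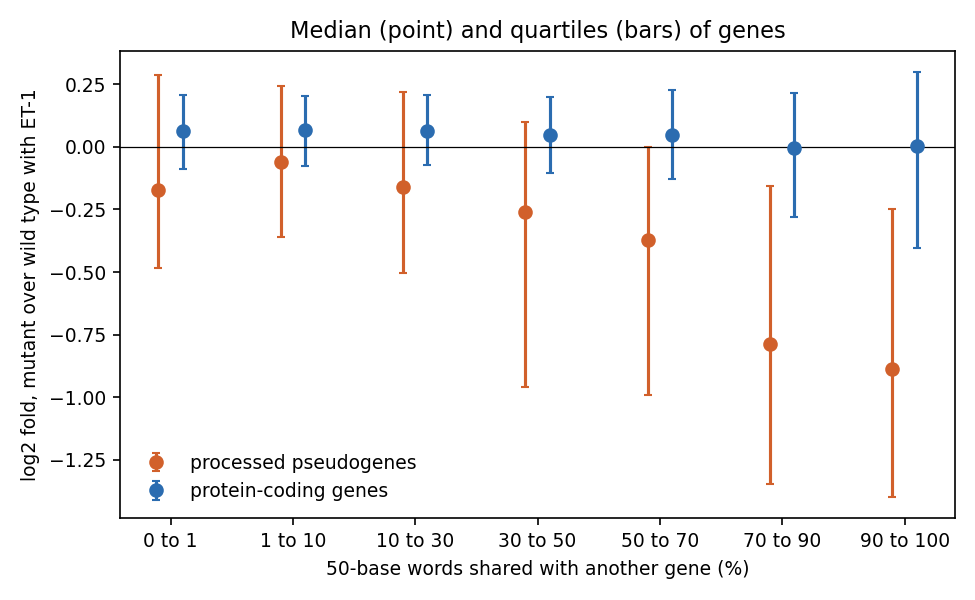
Log2 fold of the Mef2c mutant over wild type, both with ET-1 (y axis), by the share of a gene's 50-base words found in another gene (x axis, %), for processed pseudogenes (orange) and protein-coding genes (blue). Points are medians over genes and bars span the quartiles; the pseudogene median went from -0.17 in the lowest class to -0.89 in the highest, and the protein-coding median from 0.06 to 0.0025.

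On chromosome 4, 24 gene models between 41755956 and 42869643 (mm9) were higher in the mutant and 6 models of the same interval were lower. The higher models had a median of 3.41 FPKM with PBS, 6.75 FPKM with ET-1 and 48.7 FPKM in the mutant. The lower models, the Ccl21 copies among them, had medians of 4.29, 8.76 and 1.37 FPKM in the same order. On chromosome 2, 7 models between 83795850 and 83833780 had a median of 28.9 FPKM with PBS, 13.1 FPKM with ET-1 and 1.03 FPKM in the mutant, and were lower in both comparisons. Both intervals were singled out after their values were seen.

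**Figure D3:**
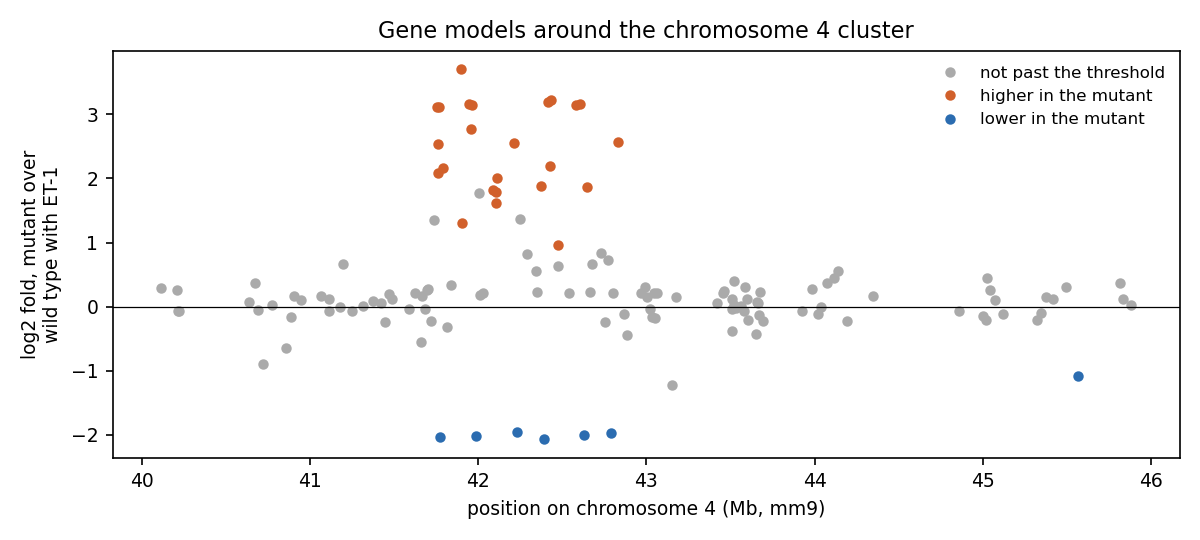
Gene models on chromosome 4 by position (x axis, Mb in build mm9) and log2 fold of the Mef2c mutant over wild type, both with ET-1 (y axis). Each point is a gene model, orange where higher and blue where lower in the mutant by the test; the 24 higher and 6 lower models of the cluster share the same interval, and 64 flanking genes with little shared sequence had a median of 0.07.

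The list of immediate early and MAP kinase feedback genes lay above the central 95% of random lists in the mutant as well. Of 28 measured, 7 rose and 0 fell (8 higher and 2 lower adjusted over the list alone; median log2 fold 0.26, percentile 100). Egr1 rose from 90.7 to 183 FPKM, Nr4a3 from 7.26 to 12.8 FPKM and Fosl2, an AP-1 component, from 1.56 to 4.08 FPKM. Of 10 Notch signalling genes, 3 rose (4 adjusted over the list alone; median 0.32, percentile 99.9), all of them repressors induced by the pathway: Hes1 from 29.4 to 52.3 FPKM, Hey1 from 12.4 to 24.2 FPKM and Heyl from 15.8 to 30.3 FPKM. Of 13 BMP signalling genes, 1 rose, Id1, an inhibitor of basic helix-loop-helix factors, from 39.3 to 60.3 FPKM, a call lost without the filter on low values (1 adjusted over the list alone; median 0.40, percentile 100). Id2 stood at 67.7 and 89.9 FPKM and Id3 at 81.7 and 109 FPKM, neither past the test.

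Lists below the central 95% in the mutant were the MEF2 list, erythroid genes, and hypoxia and glycolysis genes. In the MEF2 list 4 of 13 fell and 1 rose (5 lower and 1 higher adjusted over the list alone; median -0.14, percentile 1.46). Besides Mef2c and Mef2d, the falls were Hdac5, a class IIa histone deacetylase, from 11.8 to 8.27 FPKM and Ppargc1a, a transcriptional coactivator of mitochondrial genes, from 2.03 to 0.688 FPKM, and the rise was Klf4. Without the filter on low values that median was -0.06 and lay inside the central 95%. Mef2c is the mutated gene, so its fall is no evidence of dependence on Mef2c, and without it, a choice made after the data were seen, the median was -0.10 and lay inside the central 95%. Of 14 hypoxia and glycolysis genes 2 fell (4 adjusted over the list alone; median -0.16, percentile 1.38): the mitophagy gene Bnip3 from 45.1 to 30.1 FPKM and the kinase gene Pdk1 from 15.2 to 11.2 FPKM. At 5 FPKM or more in either group this list lay inside the central 95% with a median of -0.17. Neither fall was called among protein-coding genes with little shared sequence. Bnip3 shares 62.4% of its 50-base words with other genes and was not tested there, and the call of Pdk1 was lost. Of 5 erythroid genes 0 passed over all genes (1 lower adjusted over the list alone; median -0.62, percentile 0.16), with the embryonic globin Hbb-y at 10.5 and 4.22 FPKM and Hba-x at 9.37 and 6.11 FPKM. With ET-1 in wild type 6 lists lay above and 3 below the central 95%, and in the mutant 3 above and 3 below.

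Among the lists inside the central 95%, single members passed the test in the mutant. In the endothelin programme 1 of 9 fell, the mutated gene Mef2c itself (2 higher and 1 lower adjusted over the list alone; median 0.0021, and 0.14 without Mef2c). Of the neural crest genes 1 of 18 rose, Tcfap2b by 1.52-fold from 26.4 FPKM, and 1 fell, Ets1 from 31.7 to 24.1 FPKM (1 and 1 adjusted over the list alone; median -0.10, percentile 2.87). At 5 FPKM or more in either group the median of the neural crest list was 0.19, of the opposite sign, and lay above the central 95%, as did the dorsal or maxillary genes (0.27) and the WNT targets (0.29). Hey1 was the 1 of 10 dorsal or maxillary genes that rose (1 adjusted over the list alone; median 0.12), Hspa5, the chaperone BiP, the 1 of 11 stress genes, from 112 to 169 FPKM (1 adjusted over the list alone; median 0.04), and Vcl, encoding vinculin, the 1 of 11 smooth muscle genes, from 31.8 to 52.3 FPKM (2 higher and 1 lower adjusted over the list alone; median 0.18). Col3a1, a fibrillar collagen, fell from 1.94 to 0.781 FPKM as 1 of 10 matrix genes (3 lower and 1 higher adjusted over the list alone; median 0.11). Hes5 was the 1 of 6 neural tube markers that rose (1 adjusted over the list alone; median 0.12), and Cd68, a lysosomal protein of macrophages, went from 5.54 to 12.4 FPKM as the single measured macrophage marker (1 adjusted over the list alone).

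No member passed the test in the mutant among 20 genes of mitosis and DNA replication (median log2 fold 0.07), 11 p53 and apoptosis genes (0.09), 8 WNT targets (0.09), 20 ribosomal proteins (0.0025) and 18 respiratory chain genes (-0.07), and 0 passed adjusted over each list alone. Of 18 G protein signalling genes 0 passed (1 lower adjusted over the list alone; median 0.01). The 3 epithelial markers had a median of -0.24 and the 4 mesodermal markers of 0.29, with 0 called on either count. Actc1 stood at 4.59 and 5.74 FPKM, Egfl7 at 1.66 and 1.18 FPKM, Csf1 at 1.58 and 2.13 FPKM and Kitl at 1.98 and 1.67 FPKM in wild type and mutant, none past the test.

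Genes both raised by ET-1 and lower in the mutant were the stated aim of the series, and 13 of 15190 genes tested in both comparisons met both conditions. They included Mef2c, Tmem121, Hs3st1, Plxna4, Grik1 and Colec12, given above. Cd200, a membrane glycoprotein of the immunoglobulin family, went from 6.32 FPKM with PBS to 14.4 FPKM with ET-1 and 3.55 FPKM in the mutant. Adam12, a membrane metalloprotease, went from 6.29 to 15.6 and 7.49 FPKM, and Mtss1, an actin-binding scaffold protein, from 13.1 to 28.7 and 15.6 FPKM. By contrast Nr4a3 was 3.77, 7.26 and 12.8 FPKM in the same order and rose in both comparisons, as did Tcfap2b and a pair of mitochondrial models, 4 genes in all. Dcx was the 1 gene lower with ET-1 and higher in the mutant (8.17, 4.69 and 8.77 FPKM). Lower in both were 13 genes, mostly unnamed models, with Cwc22 among them (31.8, 19.7 and 14.3 FPKM). As no mutant was given PBS, none of these patterns shows whether a response to ET-1 depends on Mef2c.

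Independent lists of these sizes would share 2.29 genes raised by ET-1 and lower in the mutant. Mef2c is the mutated gene, so its fall is no evidence of dependence, and without it 12 genes remained, against 2.25 for independent lists. A simulation without any effect, in which the ET-1 wild-type group was shared, gave 0.26 on average and at most 2 in 100 runs. For the opposite pattern the values were 0.228 and 0.28, for genes higher in both 0.652 and 0, and for genes lower in both 0.802 and 0. The shared group was a single value and could not be split, so part of the excess over 2.29 may come from the shared group. At an unadjusted p under 0.05, a threshold added after the data were seen, 68 genes were raised by ET-1 and lower in the mutant, where independent lists gave 27.8 and the simulation with a shared group gave 73.1 on average. In the authors' deposited table, 406 genes were listed as induced and 73 of them (18.0%) as Mef2c dependent. For that list from the authors' deposited table, independent lists gave 26.0 genes and the simulation 84.6 on average. Under that setting the opposite pattern held 48 genes, against 84.2 in the simulation. Higher in both were 32 and lower in both 76, against 0.11 each in the simulation. The simulation takes p as uniform, while 728 ET-1 p-values lay under 0.05 where 893 would if p were uniform. It thus cannot tell how much of the 68 or the 73 came from the shared group.

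**Figure D4:**
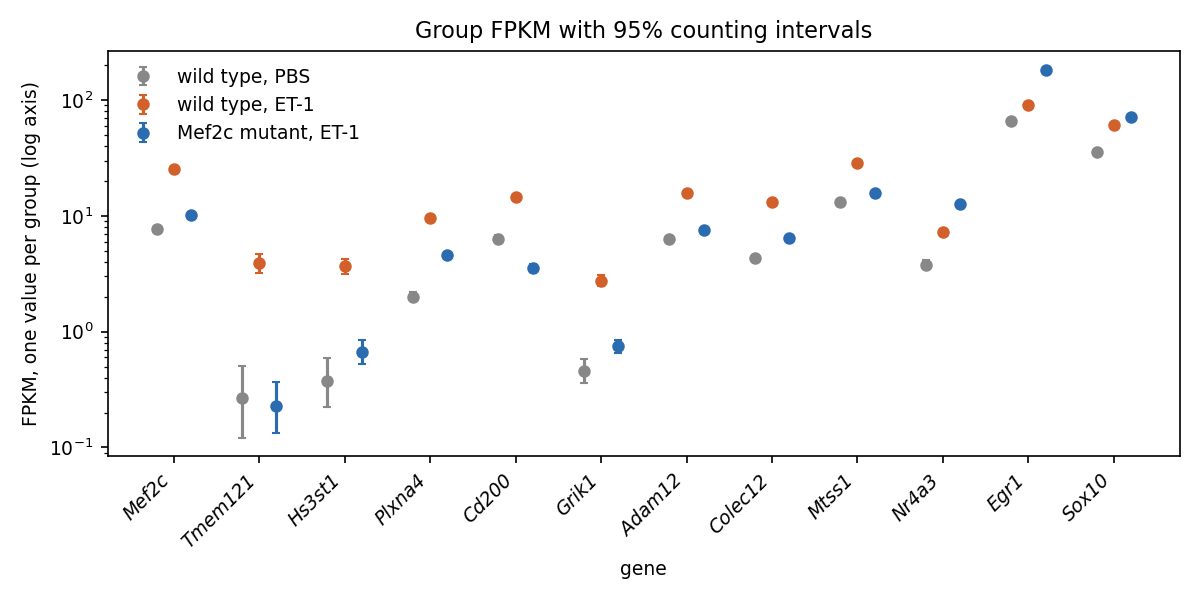
FPKM (y axis, log scale) of named genes (x axis) in wild type with PBS (grey), wild type with ET-1 (orange) and the Mef2c mutant with ET-1 (blue). Each point is a single value per group and bars are 95% counting intervals; Mef2c stood at 7.71, 25.2 and 10.1 FPKM, while Nr4a3 was highest in the mutant at 12.8 FPKM.

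The mutant given ET-1 was also compared with wild type given PBS, where no test was possible and treatment and genotype both differed. Genes called for ET-1 were chosen on the same PBS value, so a simulation without any effect, in which that value was shared, is given beside each count. Of the 60 genes raised by ET-1, 57 (95%) were above PBS in the mutant, against 98.1% of 207 genes in the simulation. Every simulated call arose by chance, so the simulated values describe selection on the shared PBS value and not genes with a true change. The share above PBS alone therefore cannot decide whether a rise remained in the mutant. At least 1.5-fold above PBS were 40 of the 60 genes (66.7%), against 23.7% in the simulation. Their median log2 fold over PBS was 0.84 in wild type with ET-1 and 0.75 in the mutant, against 0.88 and 0.40 in the simulation. Thbs1 stood at 3.48, 13.8 and 16.1 FPKM, Gfra3 at 2.15, 8.35 and 8.15 FPKM, and Sox10 at 35.7, 61.0 and 70.9 FPKM. The 13 genes raised by ET-1 and lower in the mutant had medians of 1.37 and 0.24 (1.01 and 0.13 in the simulation), and 10 of them (76.9%) were above PBS in the mutant, against 84.6% in the simulation. Of the 22 genes lowered by ET-1, 21 (95.5%) were below PBS in the mutant, against 97.8% in the simulation, with medians of -0.99 and -2.12 (-0.90 and -0.44 in the simulation). The 13 unnamed models among them, the 7 of chromosome 2 included, had medians of -1.08 and -3.71, and the 9 named genes -0.66 and -0.60. Over 15453 genes, 157 were at least 2-fold higher and 491 at least 2-fold lower in the mutant than with PBS.

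Several textbook genes of the endothelin programme were too low to compare. The homeobox gene Dlx5 held the whole numbers 1 with PBS and 3 with ET-1 in place of FPKM, and 1.06 FPKM in the mutant. Dlx3 held 3 and 6 and then 0.186 FPKM, and Edn1, which encodes ET-1 itself, 0 and 2 and then 0.329 FPKM. Dlx6 held whole numbers of 0, 0 and 1, the bHLH gene Hand2 5, 3 and 2, and the homeobox gene Gsc 0 in all groups. The bHLH gene Hand1 stood at 0.653, 0.228 and 0.224 FPKM, under the 1 FPKM filter. Ednra, the endothelin A receptor gene, was at 3.45, 3.85 and 4.88 FPKM and passed neither test (fold 1.12, interval 0.970 to 1.28 with ET-1; 1.27, interval 1.13 to 1.42 in the mutant).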

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

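Of the tests in this part, the search for genes with mixed units, the sum of reads over the chromosome 4 copies and the question of a strain or copy number variant were chosen only after the result was seen. In 1321 genes the wild-type values were whole numbers while the mutant held FPKM with a p under 1, and these entered no comparison. After adjustment over these genes alone, 2 stood out with an adjusted p under 0.05 computed from the authors' deposited table. 4930466F19Rik, on chromosome 4 at 42594761 to 42595153 (mm9), held 16.2 FPKM in the mutant against whole numbers of 1 with PBS and 2 with ET-1, where 126 reads would be expected with ET-1 at the mutant level. Aass, an enzyme gene of lysine breakdown on chromosome 6 at 23022173 to 23082986 (mm9), held 1.03 FPKM in the mutant against whole numbers of 4 and 9, where 78.1 reads would be expected with ET-1.

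4930466F19Rik lies within the chromosome 4 interval in which 24 copy models were higher in the mutant, and summed over 45 copy models the level was 511 RPM (reads scaled to the group's total) with PBS, 676 RPM with ET-1 and 2251 RPM in the mutant, a ratio of 3.33 between the mutant and ET-1 wild type. A ratio above 2 had been set as evidence against reads moving between copies of the cluster. However, reads may have been counted in several genes, so the sum need not be a count of distinct reads, and that explanation stays open. The 64 flanking genes with little shared sequence had a median log2 fold of 0.0666 (bootstrap interval -0.01 to 0.12), which argues against a change of the whole neighbourhood. A strain or copy number variant of the cluster may also differ between the groups, and it cannot be told apart from an effect of the Mef2c genotype, since expression in 24 models gives no genotype. A different treatment of reads that match several places, weighed for processed pseudogenes under the other observations, stays open here too, and so does an effect of Mef2c itself.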

How the results depend on the processing

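The alternatives could hardly reverse the direction of a called gene, so that directions held is no sign of robustness. Thresholds and filters leave the log2 fold unchanged, a pseudocount cannot turn its sign, and re-centring moved it by 0.0148 with ET-1 and 0.0503 in the mutant. The log2 fold of Mef2c was 1.58 to 1.70 with ET-1 and -1.31 to -1.24 in the mutant. The counts of calls moved with the threshold. For ET-1, 60 genes higher and 22 lower became 170 and 99 at an unadjusted p under 0.01, and 22 and 11 with a fold of at least 2. For the mutant, 183 higher became 108 at an adjusted p under 0.01 and 300 at an unadjusted p under 0.01, and 183 and 580 became 60 and 353 with a fold of at least 2. At an unadjusted p under 0.05, chosen after the data were seen, the counts were 384 and 310 for ET-1 and 688 and 1100 for the mutant. Protein-coding genes with little shared sequence, also chosen then, gave 10 lower for ET-1 and 57 higher and 48 lower for the mutant with p adjusted over them alone, and 8, 103 and 88 of the calls over all genes were among them. The authors' deposited table listed 406 induced genes.

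The overlap of 13 genes became 27 at an unadjusted p under 0.01, 6 with a fold of at least 2, 68 at an unadjusted p under 0.05 and 73 in the authors' deposited table. The opposite pattern of 1 gene became 14, 0 and 42 under the first 3 of these settings. The number given by chance was 2.29 for independent lists and 0.26 in the simulation, since the simulation holds no effects. Against PBS, 157 genes higher in the mutant became 402 with a pseudocount of 0.1 and 805 at 1.5-fold, and 491 lower became 1098 at 1.5-fold. At 5 FPKM or more in either group, 6 lists in place of 3 lay above the central 95% in the mutant, and the neural crest list had a median of 0.19 in place of -0.10; the cause was not tested. Of 210 values of single lists, 198 kept their side of the central 95%, 5 moved inside it and 7, the neural crest list among them, moved outside it; 10 changed sign, that list and 9 inside the central 95% under both settings. Of 732 values of single genes, all called under the main settings, 664 kept their side of the threshold and 68 lost the call. The unadjusted thresholds loosened the call, and the pseudocount and re-centring left p unchanged, so these alternatives could hardly undo it. Genes that a setting left out were not counted. The 664 are therefore no measure of robustness.

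No paired analysis was possible because the table held a single value per group without replicate numbers. For the same reason leaving out each replicate, quantile normalization, fits on single samples and other count tests were not run. A significance mark by the authors for all genes was not used here, and their deposited fold was compared for Mef2c alone. The lower depth of the wild-type groups limited genes near 1 FPKM.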

Other observations

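Of the tests in this part, those of the depth ratio, of small and structural RNA and of fewer dividing cells were chosen only after the result was seen. Of 38 mitochondrial genes, 12 were higher and 3 lower in the mutant than in wild type with ET-1 (median log2 fold 0.37). The ATP synthase subunit gene mt-Atp6 was at 742 FPKM with PBS, 634 FPKM with ET-1 and 1239 FPKM in the mutant. The 3 lower were the complex I subunit genes mt-Nd6 (1638, 1627 and 711 FPKM) and mt-Nd5 (1865, 1690 and 1199 FPKM) and the transfer RNA gene mt-Tv (1245, 1577 and 1133 FPKM). The cytochrome oxidase gene mt-Co1, at 2886, 3167 and 3771 FPKM, was not called. These genes were chosen after their values were seen.

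Protein-coding genes with little shared sequence that were called in the mutant included single genes outside the fixed lists, each named after its values were seen and not as a group. Lower were the collagen gene Col5a2 (6.88 to 3.23 FPKM), the hyaluronan receptor gene Cd44 (3.21 to 1.73 FPKM), the receptor tyrosine kinase gene Kit (15.2 to 9.51 FPKM) and the sugar transporter gene Slc2a3 (85.7 to 59.5 FPKM). Gclm, a subunit of the enzyme that limits glutathione synthesis, went from 12.7 to 4.65 FPKM. Higher were the bHLH genes Neurod4 (9.15 to 15.8 FPKM) and Olig3 (23.9 to 43.2 FPKM). Among genes raised by ET-1 were also the cadherin gene Cdh6 (21.3 to 34.3 FPKM), the collagen gene Col5a1 (5.91 to 12.1 FPKM) and Thbs2 (9.83 to 21.7 FPKM).

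Processed pseudogenes were lower in the mutant in 282 of 1127 cases. Those with at least 50% of their 50-base words in another gene lay 0.52 lower on the log2 scale than those under 10% (difference -0.52, bootstrap interval -0.71 to -0.39), so reads shared with near-identical transcripts that were counted differently in the mutant group are a candidate explanation. Their 245 protein-coding parent genes had a median of 0.0231 (interval -0.01 to 0.05), while the 340 pseudogenes of these parents had a median of -0.77. These values argue against lower parent transcripts for the set as a whole. Of the parents 14 were lower and 1 higher, against 126 lower and 127 higher of 11808 protein-coding genes outside the histone clusters. Protein-coding genes sharing at least 50% of their words, histone genes included, were lower in 48 and higher in 5 of 449 cases. The skew of the parents may thus come with shared sequence, and whether single pseudogenes follow a lower parent was not tested. The mutant group was 2.37 times as deep as wild type with ET-1, and a different run or read length of that group cannot be told apart from the genotype, since every mutant library is in a single group. Among the barcodes in the labels, 2 were each given to 2 library names, which would need separate runs or lanes, and both pairs joined a library named EK (2 of 3 such names) to a library named E or N, but the labels do not tie the names to samples.

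Histone cluster genes were lower in the mutant in 49 of 62 cases, with a median log2 fold of -0.84. Other small and structural RNA models had a median of 0.0150 (247 models, bootstrap interval -0.07 to 0.08), which argues against a fall of these models as a set. They are not mRNAs, and reads of other genes may be counted in them, so a loss of mRNAs without a poly(A) tail stays open. The 20 genes of mitosis and DNA replication had a median of 0.0734 (interval 0.01 to 0.18), which argues against fewer dividing cells. Shared sequence may contribute, since 23 of the 62 share at least 50% of their words, but of the 5 that share under 10%, 2 were still lower. An effect of Mef2c on histone transcripts was not tested apart from the group difference itself.

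Whether the MEF2 motif mark of the induced list follows gene length or Mef2c dependence was tested as a hypothesis. Of the 406 induced genes in the authors' deposited table, 338 carried the mark, with a median gene span of 37.9 kb against 25.5 kb for the other 68, a ratio of 1.49 (bootstrap interval 0.966 to 3.59; two-sided permutation test, p = 0.0772, 100000 resamples). A p above 0.05 had been set beforehand as evidence against the length hypothesis, and that bound was wrong, because a missed threshold excludes nothing and the interval includes a ratio of 1.2. The bound was replaced after the value was seen. The mark was present in 58 of 73 genes listed as Mef2c dependent in the authors' deposited table (79.5%) and in 280 of 333 others (84.1%), an odds ratio of 0.733 (interval 0.375 to 1.498, Fisher's exact test, p = 0.386). Neither hypothesis could be decided from these genes.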
